A study of Mus musculus with 30 samples.

How the data were processed

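The deposited values were linear MAS5 signal intensity units, 1 per probe set and array, named as MAS5 in the submitters' processing notes; the MAS5 version is not given in the sources used here. The arrays were Affymetrix MG-U74Av2 with biotin-labelled total RNA of microdissected olfactory epithelium, per the labels and the probe table. The 2% trimmed means of the 30 arrays lay between 1500.7 and 1500.9, so scaling by the authors was read from the values. No detection calls or raw intensities were used here.

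Of 12488 probe sets 66 were array controls. Signals below 113.7, the 25th percentile of all signals pooled, were set to that floor before taking log2, since low MAS5 signals are mostly background. A probe set was tested if at least 3 arrays exceeded the pooled median of 572, which kept 6968 and left out 5454. In the probe table each of 10833 probe sets had 1 gene, 396 several and 1193 none. Of the tested ones 6320 had 1 gene, standing for 5396 genes with 1 probe set each, chosen as the brightest on average. Gene positions and names came from the GRCm38.p6 assembly, with 10815 probe sets matched by gene identifier and 0 symbols updated.

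Group means of the 10 genotype and time groups were fitted in limma 3.58.1 under R 4.3.3 with moderated variances, and contrasts were taken between them. P-values were two-sided and Benjamini-Hochberg adjusted over the tested probe sets of each contrast, with a threshold of 0.05. The interaction was the moderated F of the 4 differences of changes. Gene lists were written before the values were seen and tested with camera on genes, with a preset correlation of 0.01 and again with the correlation estimated, and adjusted over the lists tested. Of 36 lists 30 had at least 5 measured genes and were tested. The T and natural killer cell, B and plasma cell, mast cell, red blood cell and skeletal muscle lists had fewer, and the sex-linked genes were only looked at as a check.

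Gene names in the text were picked by a rule set before the values were seen. For each contrast it took the 5 largest rises and 5 largest falls past the threshold whose arrays did not overlap, and 12 of each over all times. It added up to 4 members of each list with the largest changes past the threshold, the 10 interaction probe sets with the smallest p, and Msr1, Omp, Gap43 and Cd68. Probe sets with several genes were not named. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

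The pipeline was tried on simulated arrays, with 100 probe sets changed 2-fold and 100 changed 4-fold among the 6968. Each probe set had its mean and within-group spread from the data, with independent normal noise and the same spread in every group. Genes that vary together and outlying arrays were not simulated, so these rates need not hold for the real arrays. For wild type at 48 h against 0 h the pipeline recovered 85.0% of the 2-fold and 97.0% of the 4-fold changes and called 5 unchanged probe sets. For the genotypes over all times it recovered 100% of both and called 14 unchanged, and for the interaction 62.0% and 94.0% with 7 unchanged. A lysosome list of 23 genes raised by 0.5 log2 was called at both correlation settings and 0 of 29 other lists were.

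Alternatives tried were no filter, a pseudocount of 16 in place of the floor, quantile normalization, the replicate number as a block, a variance trend with robust moderation, fits of only the groups compared, and each array left out in turn. Fits without the mutant-labelled 2 h arrays, and with only replicate 2 of them, were added after the values were seen. Changes between times other than 0 h were not analysed here.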

Results

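The data were gene expression arrays of mouse olfactory epithelium, the sheet of sensory neurons, supporting cells and basal stem cells that lines part of the nasal cavity. The series followed the tissue after bilateral olfactory bulbectomy, the surgical removal of both olfactory bulbs, which are the brain targets of olfactory sensory neuron axons. It used 6-week-old mice labelled wild type or mutant for SR-A, the class A macrophage scavenger receptor encoded by Msr1. Arrays were made at 0, 2, 8, 16 and 48 h, with 3 arrays per genotype and time, 30 in all. The labels do not say whether the 0 h mice were unoperated or sampled directly after surgery, so that what the 0 h baseline stands for is not known here. The labels do not say that every array came from a separate mouse, so p-values measure the spread between these arrays, which may in part be technical. All 30 arrays had been scaled alike, with a 2% trimmed mean signal between 1500.7 and 1500.9. The number of arrays limits the precision of each value. Changes below are log2 differences of group means ± their standard error, from 3 arrays per group unless another number is given, and a p is Benjamini-Hochberg adjusted over the 6968 tested probe sets. Where arrays of the dimmer group, and none of the brighter one, lay at or below the floor of 113.7, a difference is given as at least that many fold.

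Msr1, the targeted gene, was higher in the arrays labelled mutant. The brighter of its 2 probe sets gave a signal of 442 ± 82.2 (SD, n = 15) in the mutant-labelled arrays and 155.4 ± 63.0 (SD, n = 15) in the wild-type-labelled arrays, at least 2.75-fold higher, with 3 of the latter at or below the floor. The lowest mutant-labelled array, at 297.5, lay above the highest wild-type-labelled array, at 295.1. The other probe set gave 225.8 ± 61.7 against 94.2 ± 35.4, a log2 difference of 0.88 ± 0.11 after flooring, with 11 wild-type-labelled arrays and 1 mutant-labelled array at or below the floor and 8 of the 30 arrays inside the range of the other label. In a two-sided permutation test of log2 signals without a floor, with 100000 resamples, both differences had p = 1e-05, the smallest these permutations can give. Both probe sets were dim and did not pass the filter on low signals. A loss of transcript would go the other way, and whether the probes lie in the deleted part of the gene is not known here, so Msr1 does not check the labels. The groups are therefore called wild-type-labelled and mutant-labelled, and every direction between genotypes below rests on those labels.

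**Figure D1:**
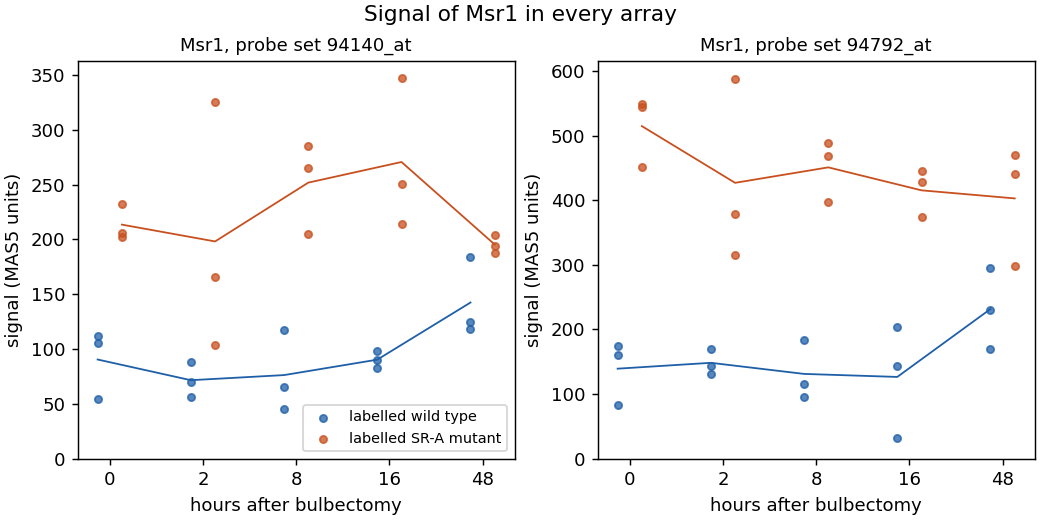
Signal of the 2 Msr1 probe sets (vertical axes, MAS5 signal units) in each of the 30 arrays by hours after bulbectomy (horizontal axes); points are arrays and lines join group means. For the brighter probe set the mutant-labelled arrays sit between 297.5 and 587.4 and the wild-type-labelled arrays between 32.6 and 295.1.

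The mutant-labelled 2 h arrays stood apart in a control of RNA quality. The control probe sets for the housekeeping gene Gapdh gave 3' minus 5' log2 differences of 5.59, 0.15 and 1.27 in replicates 1, 2 and 3 of that group, while the other 27 arrays lay between -0.31 and -0.13. A high value can mark RNA that is degraded or was copied only near its 3' end. The actin control probe sets gave 2.27, 1.02 and 0.43 against 0.45 to 1.11 in the other arrays, so by that control only replicate 1 stood above the rest. Every comparison that uses these 3 arrays carries that difference, and they also widen the shared estimate of spread. Counts from a fit without them, an alternative added after seeing the data, are given where they moved a count by over 1.5 times.

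**Figure D2:**
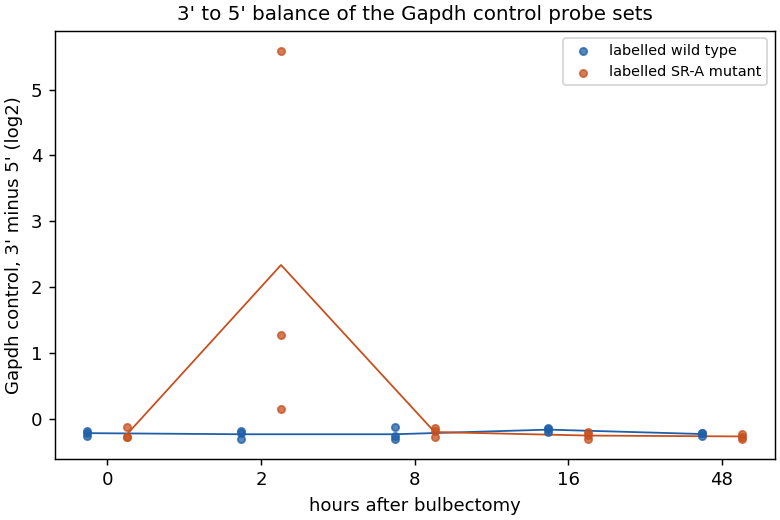
Difference between the 3' and 5' control probe sets of Gapdh (vertical axis, log2) in each array by hours after bulbectomy (horizontal axis); points are arrays and lines join group means. The 3 mutant-labelled 2 h arrays lie at 5.59, 0.15 and 1.27, above every other array.

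The first question was which genes change in the wild-type-labelled epithelium after its target is removed. At 2 h, 40 probe sets changed, 30 up and 10 down. Srxn1, which repairs oxidised peroxiredoxins, fell by 1.29 ± 0.24 (adjusted p = 0.0295; -0.40 on its other probe set), and Fkbp5, a glucocorticoid-induced co-chaperone, fell by 1.10 ± 0.21 (adjusted p = 0.0295). The synaptic vesicle gene Rab3a (-1.29 ± 0.30) and the sperm-tail and centriole gene Odf2 (-1.13 ± 0.25) fell too. Pold2, a DNA polymerase subunit, rose by 1.46 ± 0.28, and the immunoglobulin heavy chain Ighm, at the floor in all 3 arrays at 0 h, was at least 7.39-fold higher (adjusted p = 0.0476), with 1 of its 2 other probe sets of opposite sign. None of the 30 gene lists tested shifted at 2 h. Leaving out wild-type-labelled 0 h replicate 1 or 3, or 2 h replicate 1, 2 or 3, gave 6, 0, 0, 0 and 1 probe sets. The limma counts at an unadjusted p under 0.05 were 907, 920 and 870 where the count was 0. The fit without the mutant-labelled 2 h arrays called 132, quantile normalization 104 and a variance trend with robust moderation 71. With the replicate number as a block 15 were called, 14 of them among the 40, and Rab3a, Odf2 and Ighm no longer passed.

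At 8 h few probe sets changed in the wild-type-labelled arrays. Ccl2, a monocyte-attracting chemokine, was at the floor at 0 h and at least 4.86-fold higher (adjusted p = 0.0109). The protease inhibitor Slpi rose by 1.58 ± 0.28 (adjusted p = 0.0109) and the iron-siderophore-binding Lcn2 by 1.43 ± 0.28 (adjusted p = 0.0179). The other probe set of each gave less, 0.47 (adjusted p = 0.469) for Slpi and 0.07 for Lcn2. Sat1, of polyamine catabolism, rose 2.82-fold and the anti-inflammatory annexin Anxa1 by 1.26 ± 0.26. Serpina3n, an acute phase serpin, rose by 1.19 ± 0.25. Odf2 fell by 1.41 ± 0.25. The Lcn2 signal was 19245.7, 18943.7 and 5808.9 in 8 h replicates 1, 2 and 3, and its change was 1.13 (adjusted p = 0.225), 1.15 (adjusted p = 0.191) and 2.00 (adjusted p = 1.42e-07) without each of them. Without replicate 3 Slpi rose by 1.93, Anxa1 by 1.75 and Serpina3n by 1.56, and without replicate 1 or 2 these 3 missed the threshold. In all, 14 probe sets passed, 12 up and 2 down. The cytokine list (15 genes, median 0.26, camera adjusted p = 6.24e-06) and the acute phase list (17 genes, median 0.21, camera adjusted p = 0.000102) shifted up. Their adjusted p = 0.102 and 0.305 with an estimated correlation. Of the acute phase genes 2 rose over all genes tested and 5 adjusted over the list alone. No cytokine gene rose over all genes tested and 4 did adjusted over the list alone. Leaving out 0 h replicate 1 or 2, or 8 h replicate 1 or 2, gave 2, 0, 3 and 4 probe sets, and leaving out 8 h replicate 3 gave 93. With 0 h replicate 2 left out, limma gave 590 at an unadjusted p under 0.05. A fit of only the 6 arrays compared gave 0, with 531 at an unadjusted p under 0.05.

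At 16 h immediate early and heat shock genes were down and interferon and acute phase genes up in the wild-type-labelled arrays. Calb1, a calcium-binding protein of many neurons, fell from a signal of 1255 ± 274.6 (SD) to the floor, at least 10.8-fold (adjusted p = 1.82e-06). The immediate early genes Nr4a1 (-2.50 ± 0.42), Atf3 (-1.75 ± 0.29) and Fos (-1.66 ± 0.33) were among 9 of 24 genes of their list that fell, with none up, and 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 6.07e-06). With an estimated correlation the adjusted p = 0.193. Heat shock genes fell in 4 of 14 cases (camera adjusted p = 0.00219, adjusted p = 0.284 with an estimated correlation), led by Hspa1a at -2.47 ± 0.46 and Hspa1b at -2.05 ± 0.45. Interferon-stimulated genes rose in 6 of 20 cases and fell in 1, and rose in 10 adjusted over the list alone (camera adjusted p = 8.50e-05). Gbp2 (1.40 ± 0.33), Ifi47 (1.37 ± 0.28) and Usp18 (1.20 ± 0.26) led them, and the adjusted p = 0.284 with an estimated correlation. Acute phase genes rose in 6 of 17 cases, among them Lcn2 (2.24 ± 0.28, but -0.09 on its other probe set) and Orm1 (at least 3.13-fold), with camera adjusted p = 0.00689 and an adjusted p = 0.45 with an estimated correlation. Lyz2 of macrophages and granulocytes rose by 1.33 ± 0.27. The immunoglobulin genes Igha (2.81 ± 0.66) and Igkv6-23 (2.99 ± 0.63) were higher than at 0 h. In all, 455 probe sets changed, 243 up and 212 down. Leaving out any 1 of the 6 arrays lowered the count by over 1.5 times, to 203, 263 and 197 without 0 h replicates 1, 2 and 3 and to 164, 269 and 208 without 16 h replicates 1, 2 and 3. A fit of only those 6 arrays called 738.

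At 48 h the wild-type-labelled epithelium showed a large inflammatory change, with 1042 probe sets past the threshold, 549 up and 493 down. The neutrophil-attracting chemokine Cxcl2 went from a signal of 107.2 ± 35.1 to 5524 ± 2240.5 (SD), at least 42.4-fold higher (adjusted p = 3.82e-06). The acute phase genes Saa3 (4.82 ± 0.35, adjusted p = 3.51e-09), Orm1 (at least 19.1-fold) and Lcn2 (3.03 ± 0.28, and 0.43 on its other probe set) rose, with 9 of 17 members of their list up, 12 adjusted over the list alone, and none down (camera adjusted p = 1.47e-10, estimated-correlation adjusted p = 0.0413). The matrix protease Mmp3 rose at least 13.8-fold and the cornified envelope gene Sprr2f by 3.60 ± 0.55. Of 8 chemokine genes 5 rose, among them Cxcl1 (2.91 ± 0.57) and Ccl2, at least 8.11-fold higher (camera adjusted p = 0.00024). Of 15 cytokine genes 6 rose, with Il1b at 2.51 ± 0.40, Il1rn at least 5.02-fold higher and Il6 at 1.54 ± 0.47 (camera adjusted p = 2.20e-07). The chemokine and cytokine calls held with an estimated correlation, at adjusted p = 0.0408 and 0.0271. Interferon-stimulated genes rose in 11 of 20 cases and macrophage genes in 8 of 17, with none of either down. Their camera adjusted p values were 2.40e-06 and 3.33e-05, and with an estimated correlation both adjusted p = 0.0811. Gbp2 (2.22 ± 0.33), Lyz2 (1.36 ± 0.27) and the macrophage lysosomal marker Cd68 (0.81 ± 0.16, adjusted p = 0.00093) were examples. Lysosomal genes rose in 10 of 23 cases (camera adjusted p = 0.000182, estimated-correlation adjusted p = 0.0271), led by the cathepsins Ctsl (0.97 ± 0.16) and Ctsh (0.89 ± 0.15). The neutrophil alarmins S100a8 and S100a9 rose by 2.09 ± 0.36 and 2.01 ± 0.38.

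Genes of mature olfactory sensory neurons fell at 48 h in the wild-type-labelled arrays. Of 11 measured, 6 fell and 1 rose (camera adjusted p = 0.00024, adjusted p = 0.0848 with an estimated correlation), and 9 fell adjusted over the list alone. The odorant transduction genes Adcy3 (-1.06 ± 0.16) and Cnga2 (-0.81 ± 0.16) fell, while the shared G protein subunit Gnb1 rose by 1.29 ± 0.26, with 1 of its 2 other probe sets near 0. Omp, the marker of mature sensory neurons, went from 29569 ± 2280 to 17240 ± 841.7 (SD), a difference of -0.78. Its standard error was 0.86 in the fit of all arrays (adjusted p = 0.602) and 0.11 without the mutant-labelled 2 h arrays (adjusted p = 3.91e-05). Gap43, a marker of immature neurons, differed by -0.26 ± 0.22 (adjusted p = 0.476). Collagen genes fell, with Col1a1 at -2.44 ± 0.25 and Col1a2 at -2.45 ± 0.22, against -0.62 and -0.09 on the other probe set of each. Of 11 fibroblast genes 5 fell, and of 7 bone and cartilage genes 4 fell (camera adjusted p = 0.000182 and 0.00125; adjusted p = 0.0811 for both with an estimated correlation). Heat shock genes fell in 8 of 14 cases and rose in 1 (camera adjusted p = 0.00024, adjusted p = 0.138 with an estimated correlation). Calb1 stayed at the floor. Leaving out wild-type-labelled 48 h replicate 1 gave 572 probe sets in place of 1042.

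**Figure D3:**
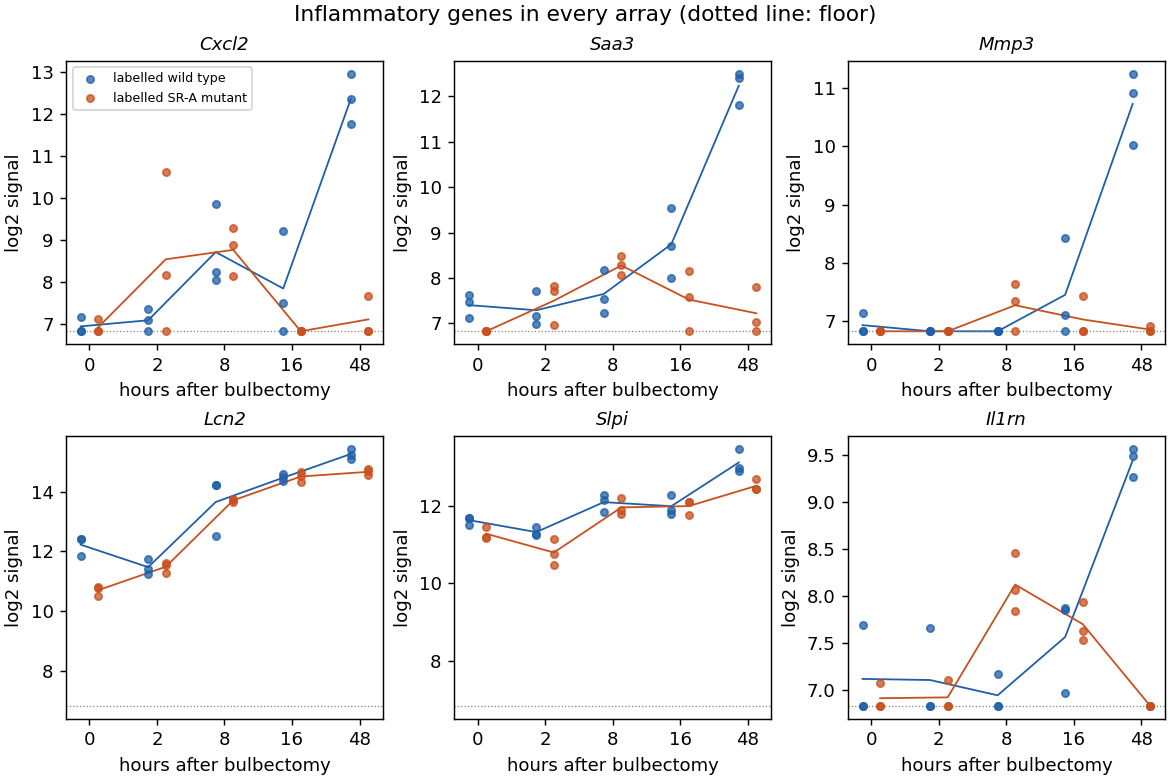
Log2 signal (vertical axes, floored at the dotted line) of 6 inflammatory genes in each array by hours after bulbectomy (horizontal axes); points are arrays and lines join group means. At 48 h Cxcl2, Saa3, Mmp3 and Il1rn are at least 37.8-fold, 32.1-fold, 14.6-fold and 6.12-fold lower in the mutant-labelled arrays, while Lcn2 and Slpi are above their 0 h level in both. Slpi too is lower in the mutant-labelled arrays at 48 h, at -0.6 (limma adjusted p = 0.0205) on the plotted probe set. Its other probe set, whose larger changes the text gives first, is at -1.15 (limma adjusted p = 0.00707).

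The same time course was then read in the mutant-labelled arrays. At 2 h, 1233 probe sets differed from 0 h, 514 up and 719 down, in arrays whose Gapdh 3' minus 5' differences of 5.59, 0.15 and 1.27 lay above all others. Omp (-4.17 ± 0.86, adjusted p = 0.00165), the arginine methyltransferase Prmt1 (at least 19.7-fold), the histone gene H2bc21 (at least 12.3-fold) and the lysosomal Psap (at least 10-fold) fell. Of 2 other Psap probe sets 1 passed in the same direction and 1 had the opposite sign. The cytoskeletal Actb rose by 2.03 ± 0.42 and Gnb1 by 1.66 ± 0.26, although its 2 other probe sets had the opposite sign. Without replicate 1 Omp differed by -2.21 and H2bc21 by -1.90, and with replicate 2 alone Omp differed by -1.04, H2bc21 by -1.82, Prmt1 by -2.97, Psap by -2.75 and Actb by 0.38 (adjusted p = 0.625). Without replicate 2 Prmt1 differed by -4.97. None of the gene lists shifted. Leaving out replicate 1, with the highest Gapdh difference, gave 510 probe sets, and leaving out 0 h replicate 2 gave 792. With replicate 2 as the only 2 h array, assumed to vary like the other groups, 320 were called, and a fit of only the 6 arrays gave 31.

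At 8 h in the mutant-labelled arrays Sprr1a, Sprr2f, Cldn4 and acute phase genes rose. The cornified envelope gene Sprr1a rose by 3.67 ± 0.49 (adjusted p = 0.000127), Lcn2 by 3.00 ± 0.28 (adjusted p = 7.53e-07), Sprr2f at least 6.59-fold and Slpi by 2.46 ± 0.28. The other probe set gave 0.32 for Lcn2 and 0.68 (adjusted p = 0.0445) for Slpi. The tight junction gene Cldn4 rose by 2.19 ± 0.47. Of 15 cytokine genes 4 rose, with the oncostatin M receptor Osmr at 1.88 ± 0.30 and Csf3 at 1.62 ± 0.35 (camera adjusted p = 1.66e-08, estimated-correlation adjusted p = 0.0244). Of 17 acute phase genes 4 rose (camera adjusted p = 1.81e-07), and of 14 heat shock genes 4 rose and 8 did adjusted over the list alone (camera adjusted p = 4.71e-06). For both, the adjusted p = 0.111 with an estimated correlation. Cryab (2.11 ± 0.32) and Hspa1b (1.79 ± 0.45) were examples. Immediate early genes fell in 6 of 24 cases and rose in 1, with Nr4a1 at -2.50 ± 0.42 and Ccn1 at -2.06 ± 0.36 (camera adjusted p = 0.00613, adjusted p = 0.446 with an estimated correlation). Cyp1a1, a target of the aryl hydrocarbon receptor, fell by 2.42 ± 0.47. In all, 133 probe sets changed, 90 up and 43 down. Leaving out 0 h replicate 2 or 3 gave 60 and 83, and leaving out 8 h replicate 1, 2 or 3 gave 63, 63 and 52.

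At 16 h and 48 h Lcn2, Slpi and Serpina3n rose and immediate early genes fell in the mutant-labelled arrays. Lcn2 rose by 3.80 ± 0.28 at 16 h (adjusted p = 6.02e-09) and 3.96 ± 0.28 at 48 h (adjusted p = 8.49e-10), Slpi by 2.82 ± 0.28 and 3.49 ± 0.28, and Serpina3n by 1.97 ± 0.25 and 2.08 ± 0.25. The other Slpi probe set rose by 0.72 (adjusted p = 0.0244) and 1.24 (adjusted p = 8.39e-05), and that of Lcn2 by 0.30 and 0.50. Nr4a1 (-3.34 ± 0.42 and -3.23 ± 0.42), Fos (-3.09 ± 0.33 and -2.83 ± 0.33) and Egr1 (-2.22 ± 0.27 and -2.14 ± 0.27) fell at the 2 times. Of the 24 immediate early genes 10 fell at 16 h and 11 at 48 h, with 1 up at each time (camera adjusted p = 1.58e-12 and 1.72e-12, estimated-correlation adjusted p = 0.0142 and 0.0145). Heat shock genes fell in 4 of 14 cases at 16 h and 8 of 14 at 48 h (camera adjusted p = 0.00347 and 2.79e-05; adjusted p = 0.346 and 0.12 with an estimated correlation). Calb1 was at the floor at 16 h, at least 9.4-fold lower, and at 600.5 ± 95.7 (SD) at 48 h. The counts were 254 probe sets at 16 h, 127 in each direction, and 660 at 48 h, 313 up and 347 down. Without 0 h replicates 1, 2 and 3 the 16 h count was 130, 102 and 111, and without 16 h replicates 2 and 3 it was 113 and 146. Without 0 h replicate 1 or 2, or 48 h replicate 3, the 48 h count was 385, 365 and 344, and fits of only the 6 arrays compared called 145 at 16 h and 204 at 48 h.

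Matrix, ciliated cell and sensory neuron genes fell and lysosomal genes rose at 48 h in the mutant-labelled arrays. Extracellular matrix genes fell in 9 of 25 cases and 12 adjusted over the list alone, none up (camera adjusted p = 2.13e-07, estimated-correlation adjusted p = 0.0386), led by the urokinase receptor Plaur (at least 3.54-fold) and Col5a2 (-1.39 ± 0.22). Lysosomal genes rose in 6 of 23 cases and fell in 1 (camera adjusted p = 0.00156, estimated-correlation adjusted p = 0.0386), with Ctsl at 0.87 ± 0.16. Ciliated cell genes fell in 3 of 7 cases, with Spa17 at -1.02 ± 0.15 (camera adjusted p = 0.00385, estimated-correlation adjusted p = 0.043). Of 11 mature sensory neuron genes 3 fell, Olfm1 (-1.17 ± 0.20) and Adcy3 (-0.80 ± 0.16) among them (camera adjusted p = 0.000593, adjusted p = 0.126 with an estimated correlation). Omp differed by -0.60, with a standard error of 0.86 (adjusted p = 0.738) in the fit of all arrays and 0.11 (adjusted p = 0.000992) without the 2 h arrays. Cd68 rose by 0.64 ± 0.16 (adjusted p = 0.0106), with the complement genes C1qc (0.99 ± 0.19) and Clu (1.59 ± 0.20). Gap43 differed by 0.12 ± 0.22 (adjusted p = 0.794).

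**Figure D4:**
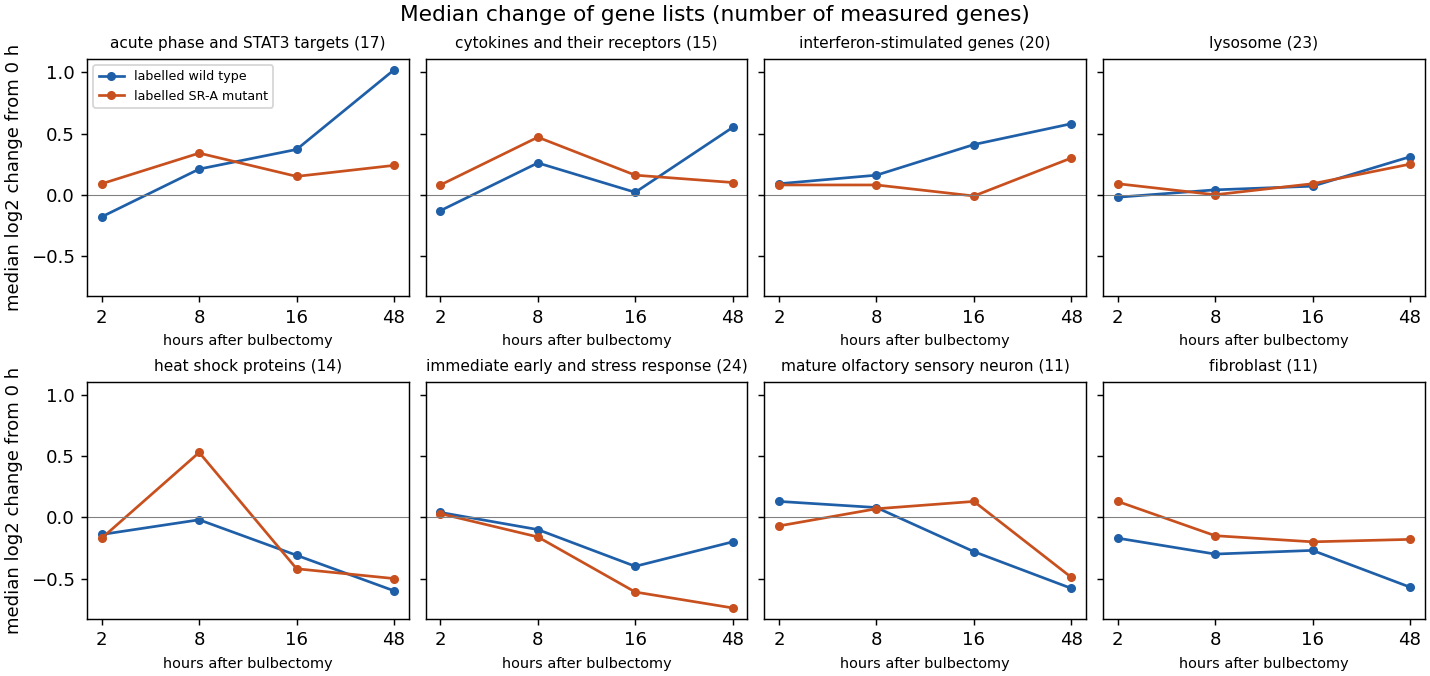
Median log2 change from 0 h (vertical axes) of 8 gene lists at 2, 8, 16 and 48 h (horizontal axes) in the arrays of each labelled genotype; each point is the median over the measured genes given in brackets, in the fit of all 30 arrays. The acute phase median at 48 h is 1.02 in the wild-type-labelled and 0.24 in the mutant-labelled arrays.

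The responses of the 2 labelled genotypes, measured on separate arrays, overlapped at 48 h. In both, 118 probe sets rose and 158 fell, where independent lists would share 24.7 and 24.6, and 11 changed in opposite directions. Across probe sets, which are not independent replicates, the changes correlated at r = 0.39. At 16 h, 34 rose and 30 fell in both, against 4.4 and 3.9 for independent lists (r = 0.27), and at 8 h 10 rose in both (r = 0.31). At 2 h no probe set changed the same way in both, 5 changed in opposite ways, and r was -0.03.

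At 0 h the arrays of the 2 labelled genotypes already differed in 1277 probe sets, 531 higher and 746 lower in the mutant-labelled ones, or 536 and 526 after quantile normalization. Immunoglobulin genes of antibody-secreting cells were the largest differences. Ighm was at the floor in the wild-type-labelled arrays and 3296 ± 1696 (SD) in the mutant-labelled ones, at least 26.8-fold higher (adjusted p = 0.000127). Igkv6-23 was higher by 4.18 ± 0.63, Igha by 3.85 ± 0.66 and Jchain, the joining chain of secreted IgA and IgM, by 2.87 ± 0.49. One of 2 other Ighm probe sets passed in the same direction. Lcn2 (-1.52 ± 0.28), Saa2 (-1.57 ± 0.48), the transcription factor Zbtb16 (-1.78 ± 0.49) and the splicing regulator Ptbp2 (-1.94 ± 0.26) were lower, with -0.41 and -0.11 on the other probe sets of Lcn2 and Ptbp2. The transcription factor Cebpb was higher by 0.74 ± 0.11 and Lyz2 by 0.86 ± 0.27. Omp differed by 0.25 ± 0.86, Gap43 by -0.14 ± 0.22 and Cd68 by -0.21 ± 0.16, none past the threshold in the fit of all arrays. The Omp standard error is widened by the mutant-labelled 2 h arrays. Its 0 h signals were 27105.5 to 31604.6 in the wild-type-labelled and 32772.4 to 36515.7 in the mutant-labelled arrays. They did not overlap, as was so for 43.2% of the tested probe sets. No gene list shifted at 0 h. Leaving out wild-type-labelled replicate 1 or 3 gave 756 and 695 probe sets, and leaving out mutant-labelled replicate 2 or 3 gave 648 and 788.

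At 2 h, 629 probe sets differed, 113 higher and 516 lower in the mutant-labelled arrays, again with the raised Gapdh differences of that group. Prmt1 (at least 19.4-fold), Omp (-3.92 ± 0.86) and the pericyte gene Rgs5 (at least 8.06-fold, and -0.62 on its other probe set) were lower, and the chemokine Cxcl1 was higher on both its probe sets, by 2.52 ± 0.60 and 2.20 ± 0.57. Without mutant-labelled replicate 1 Omp differed by -1.96 and Rgs5 by -1.91, and with replicate 2 alone by -0.80 and -1.59. Prmt1 differed by -2.94 with replicate 2 alone and -4.95 without it. Without replicate 2 the Cxcl1 differences were 1.68 (adjusted p = 0.0432) and 1.61 (adjusted p = 0.0753). The immature neuron list was lower (4 of 15 genes, camera adjusted p = 0.00171) and the nasal gland and lysosome lists higher (camera adjusted p = 0.0174 and 0.00786). With an estimated correlation their adjusted p = 0.448, 0.448 and 0.166. The count was 360, 368 and 372 without wild-type-labelled 2 h replicates 1, 2 and 3, 277 without mutant-labelled replicate 1 and 981 without replicate 2. With replicate 2 alone it was 203, and in a fit of only the 6 arrays 23.

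At 8 h, 205 probe sets differed, 99 higher and 106 lower. Sprr1a was higher by 2.27 ± 0.49 and the cytosolic chaperone Hsp90aa1 by 0.69 ± 0.17. The heat shock list was higher (1 of 14 genes over all genes tested, 5 adjusted over the list alone, camera adjusted p = 2.84e-05), with an adjusted p = 0.563 with an estimated correlation. At 16 h, 587 differed, 231 higher and 356 lower. The antigen presentation genes H2-Ab1 (-1.19 ± 0.25) and Cd74 (-1.03 ± 0.22) were lower, with 3 of 9 class II genes lower (camera adjusted p = 0.0413). So were the interferon-induced GTPases Ifi47 (-0.93 ± 0.28) and Irgm1 (-0.92 ± 0.19), with 3 of 20 interferon genes lower (camera adjusted p = 0.0282), and the basal cell integrin Itga6 (-1.06 ± 0.17). Both lists had an adjusted p = 0.812 with an estimated correlation. Omp signals at 16 h were 23186.9 to 26268.7 in the wild-type-labelled and 35961.7 to 40154.6 in the mutant-labelled arrays. They did not overlap, as was so for 34.7% of the tested probe sets. The 8 h count was 50 without wild-type-labelled replicate 3, 127, 47 and 79 without mutant-labelled replicates 1, 2 and 3, and 477 without the mutant-labelled 2 h arrays. The 16 h count was 354, 277 and 223 without wild-type-labelled replicates 1, 2 and 3, and 227 and 302 without mutant-labelled replicates 2 and 3. Fits of only the 6 arrays called 14 at 8 h and 373 at 16 h.

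At 48 h acute phase, cytokine and chemokine genes were lower in the mutant-labelled arrays. Cxcl2 was at 129.4 ± 67.1 (SD) in the mutant-labelled arrays and 5524 ± 2240.5 in the wild-type-labelled ones, at least 37.8-fold lower (adjusted p = 1.44e-05). Saa3 was at least 32.1-fold lower (adjusted p = 1.61e-09), and Sprr2f, Mmp3, Il6 and Il1b were lower too, by at least 20.7-fold, 14.6-fold, 10.6-fold and 8.22-fold. The other neutrophil chemokine Cxcl1 was at least 16-fold lower. Il1rn was at the floor in the mutant-labelled arrays, at least 6.12-fold lower. Of 17 acute phase genes 8 were lower and none higher (11 adjusted over the list alone, camera adjusted p = 1.05e-07). So were 6 of 15 cytokine genes (camera adjusted p = 1.17e-05) and 3 of 8 chemokine genes (camera adjusted p = 0.0089), and 7 of 24 immediate early genes, with Fos at -1.52 ± 0.33 (camera adjusted p = 0.00119). With an estimated correlation the adjusted p = 0.19, 0.156, 0.19 and 0.244 for these 4 lists. S100a9 (-2.08 ± 0.38), S100a8 (-1.94 ± 0.36) and the macrophage elastase Mmp12 (-1.91 ± 0.33) were lower, while Cd68 differed by -0.37 ± 0.16 (adjusted p = 0.108).

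The mutant-labelled arrays were higher at 48 h in other groups. Ighm was at least 20.9-fold higher, Igha was higher by 4.39 ± 0.66 and Jchain by 2.97 ± 0.49. The small collagen-binding proteoglycan Fmod was at least 6.24-fold higher and Col1a1 and Col1a2 were higher by 1.71 ± 0.25 and 1.32 ± 0.22 (0.89 and -0.26 on their other probe sets), in a fibroblast list with 4 of 11 genes higher (camera adjusted p = 0.00306). Sustentacular cell and xenobiotic metabolism genes were higher in 7 of 21 cases, led by the cytochrome Cyp1a2 (1.17 ± 0.20) and the monooxygenase Fmo1 (0.89 ± 0.13), with camera adjusted p = 0.00662 and a median of 0.23, or 0.08 after quantile normalization. For both lists the adjusted p = 0.244 with an estimated correlation. Omp differed by 0.42, with a standard error of 0.86 (adjusted p = 0.805) in the fit of all arrays and 0.11 (adjusted p = 0.00905) without the mutant-labelled 2 h arrays. In all, 1136 probe sets differed, 504 higher and 632 lower. The count was 631 without wild-type-labelled replicate 3, 747 without mutant-labelled replicate 2, and 339 in a fit of only the 6 arrays.

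**Figure D5:**
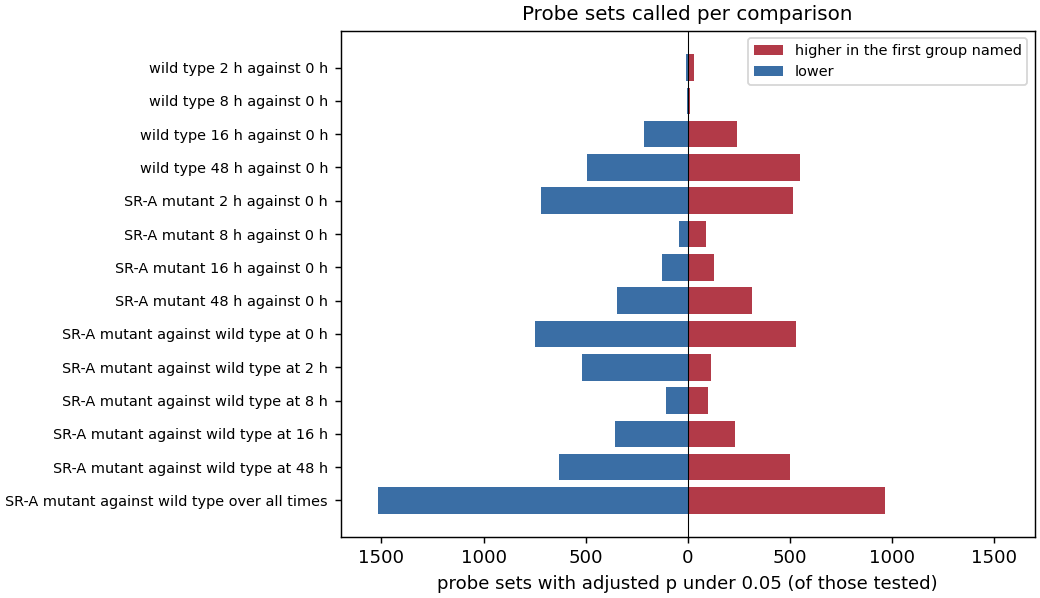
Probe sets past an adjusted p of 0.05 (horizontal axis, of 6968 tested) in each comparison (vertical axis), with those higher in the first group named to the right of 0 and those lower to the left. The bars run from 14 probe sets for wild type at 8 h against 0 h to 2485 for the genotypes over all times.

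Averaged over all times, 2485 probe sets differed between the labelled genotypes, 967 higher and 1518 lower in the mutant-labelled arrays. After quantile normalization the split was 1067 higher and 1072 lower. Ocel1 was higher by 1.70 ± 0.05 (adjusted p = 2.99e-17) and Fam32a by 1.09 ± 0.08, while Colgalt1, a collagen galactosyltransferase (-1.34 ± 0.08, adjusted p = 2.54e-11), the fatty acid transporter Slc27a1 (-1.62 ± 0.22, with 2 mutant-labelled arrays and 1 wild-type-labelled array at the floor), the chromatin repressor subunit Gatad2a (-1.07 ± 0.08) and Zfp617 (-1.05 ± 0.10) were lower. These 6 genes lie on chromosome 8, as Msr1 does. For Gatad2a 1 of 2 other probe sets passed in the same direction and 1 had the opposite sign. Nnt, the mitochondrial transhydrogenase that carries a deletion in the C57BL/6J strain, was lower (-1.21 ± 0.07, adjusted p = 2.32e-11), at 356.3 ± 44.6 against 889.8 ± 150.6 (SD) at 0 h. The labels do not give the strain, so any difference in strain background is part of every genotype difference here. Igkv6-23 (2.32 ± 0.28), Igha (2.18 ± 0.30) and Jchain (1.49 ± 0.22) were higher, and Mmp12 (-1.08 ± 0.15) and Ptbp2 (-1.07 ± 0.11, and -0.04 on its other probe set) lower. Sustentacular cell genes were higher in 10 of 21 cases and lower in none, with a median of 0.16, or 0.06 after quantile normalization (camera adjusted p = 0.00526, adjusted p = 0.768 with an estimated correlation); without the mutant-labelled 2 h arrays the camera adjusted p = 0.0534. Omp differed by -0.49 ± 0.38 (adjusted p = 0.331) over all times and was higher by 0.36 ± 0.05 (adjusted p = 2.35e-05) without the 2 h arrays of the mutant label. Gap43 differed by -0.13 ± 0.10 and Cd68 by -0.10 ± 0.07, neither past the threshold. The metallothioneins Mt1 and Mt2 were higher by 0.19 ± 0.05 and 0.21 ± 0.05, but differed by -0.03 each after quantile normalization.

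Genes near Msr1 were called more often than others. By gene positions of the GRCm38.p6 assembly, 26 of 51 measured genes within 20 Mb of Msr1 differed over all times, against 1821 of 5337 others (odds ratio 2.01, 95% interval 1.11 to 3.64, two-sided Fisher's exact test p = 0.0168). Within 10 Mb it was 15 of 21 (odds ratio 4.82, Fisher's exact p = 0.000702) and within 40 Mb 58 of 138 (odds ratio 1.40, Fisher's exact p = 0.0564). On the rest of chromosome 8, 76 of 239 genes differed (odds ratio 0.889, Fisher's exact p = 0.443). The 4 chromosome 8 genes with differences over 2-fold in this one-probe-set-per-gene table, Ocel1, Slc27a1, Colgalt1 and Zfp617, lay together 31.8 to 32.3 Mb from Msr1.

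Whether the response differed between the labelled genotypes was tested directly as an interaction. The moderated F over 4 times called 1026 probe sets, and 415 without the mutant-labelled 2 h arrays, 354 of them shared. At 48 h, 199 probe sets changed differently. Saa3 (adjusted p = 1.25e-05), Mmp3 and Il1rn rose in the wild-type-labelled arrays. In the mutant-labelled arrays their log2 means went from 6.83, 6.83 and 6.91 at 0 h to 7.22, 6.86 and 6.83 at 48 h. The size of the difference is not exact since mutant-labelled 0 h arrays of all 3 genes lay at the floor. The leukocyte receptor Lilr4b rose less in the mutant-labelled arrays (-2.02 ± 0.28), and Cebpb fell in them and rose in the others (-1.23 ± 0.16). Lilr4b also differed at 2 h, in the other direction (1.12), and Cebpb in the same direction at 2 h (adjusted p = 0.000684) and 16 h (-0.95, adjusted p = 0.0316). At 16 h, 8 probe sets changed differently, 56 without the mutant-labelled 2 h arrays. At 8 h, limma called 0, with 572 at an unadjusted p under 0.05. At 2 h, 741 did, in the arrays with raised Gapdh differences, among them Prmt1, Psap, Lasp1, the vesicle fusion gene Ykt6 and the G protein gene Gnao1. All 5 were lower in the mutant-labelled arrays, with log2 means between 7.11 and 7.55 near the floor of 6.83, so their sizes are not exact. Of the gene lists, acute phase genes changed less at 48 h in the mutant-labelled arrays (6 of 17, median -0.81, camera adjusted p = 1.54e-06), as did cytokine genes (3 of 15, median -0.66, camera adjusted p = 1.09e-05). Immediate early genes fell more in them (5 of 24, median -0.49, camera adjusted p = 1.54e-06). With an estimated correlation the adjusted p = 0.145, 0.101 and 0.101. The count of 1026 was 683 and 676 without wild-type-labelled 2 h replicates 1 and 2.

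Over the 14 contrasts above 72 list calls were made with the preset correlation and 10 with an estimated one. Of 100 assignments of the arrays to groups, the real one among them, 26 gave at least 72.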

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

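The tests of RNA quality, flanking DNA, batch, label exchange and macrophage content below were chosen after the results were seen, apart from the count of genes near Msr1 and the redrawn groups, which were set beforehand.

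A difference between the labelled genotypes in the change from 0 h was found by the interaction F in 1026 probe sets, and in 741 probe sets at 2 h, 8 at 16 h and 199 at 48 h. The 10 genes with the smallest p of that F differed at 48 h in Saa3 (-4.43), Mmp3 (-3.76), Lilr4b (-2.02), Il1rn (-2.41) and Cebpb (-1.23) and at 2 h in Ykt6 (-2.28), Psap (-3.05), Lasp1 (-2.87), Prmt1 (-4.46) and Gnao1 (-1.65). Lilr4b also differed at 2 h, in the other direction (1.12), and Cebpb in the same direction at 2 h (adjusted p = 0.000684) and 16 h (-0.95, adjusted p = 0.0316). All but Lilr4b and Cebpb had a group mean near the floor, so their sizes are not exact. Gene lists differed in their change in 1 case at 8 h, heat shock proteins, and in 4 at 16 h, where immature sensory neuron genes had a median difference of 0.33 and macrophage, interferon and ciliated cell genes of -0.40, -0.46 and -0.40. At 48 h 9 lists differed, among them chemokines at -0.91, acute phase genes at -0.81 and cytokines at -0.66. With an estimated correlation the adjusted p at 8 h was 0.831, and the smallest at 16 h and 48 h were 0.181 and 0.101. Signals of control probe sets that no comparison uses gave the Gapdh differences of 5.59, 0.15 and 1.27 in the mutant-labelled 2 h arrays, where those of actin were 2.27, 1.02 and 0.43.

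Weighed first were the calls in the mutant-labelled 2 h arrays. If RNA quality made them, the difference between the worst array and a better one should run along the same probe sets as the change of the best array, and the 2 correlated at 0.23 across probe sets, in line with RNA quality as a cause of part of the change. An early response of the mutant-labelled mice is the biological explanation. With replicate 2 as the only 2 h array 320 probe sets were called, but its own Gapdh difference of 0.15 was also above all other groups, while its actin difference of 1.02 lay inside their range, so RNA quality and an early response cannot be told apart.

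Weighed second was the genotype difference over all times. As a whole cause that acts only on nearby genes, DNA flanking the targeted allele was not borne out. Within 20 Mb of Msr1 lay 26 called genes, and 1821 lay elsewhere. The 5.5% of called genes on its chromosome decides nothing more. With so many calls, that chromosome holds too few measured genes for a large share. Effects of flanking DNA on genes of other chromosomes were not tested. The odds ratio of 2.01 within 20 Mb went the way that flanking DNA as the cause of calls there predicts. A difference in RNA quality at 0, 8, 16 and 48 h was not borne out either, with a mean Gapdh difference of -0.03 between mutant-labelled and wild-type-labelled arrays. In 13 of 15 mutant-labelled arrays the highest signal lay above that of every wild-type-labelled array, so separate batches and the genotype, the biological explanation, cannot be told apart. The labels do not give the strain, so strain background was not tested and stays open.

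Weighed last was the higher Msr1 in the mutant-labelled arrays. For the brighter probe set 0 of 30 arrays lay inside the range of the other genotype, but the gap was smaller than the SD of either label. For the dimmer one 8 of 30 did, so by Msr1 alone single wrong labels and right ones cannot be told apart. Ocel1 and Colgalt1, named for large differences over all times, separated all 30 arrays. Ocel1 lay at 425.4 to 635.9 in the wild-type-labelled and 1429.0 to 1990.5 in the mutant-labelled arrays. Colgalt1 lay at 1348.7 to 2041.7 and 455.8 to 818.9. Both genes were picked by these same labels and lie 31.8 and 32 Mb from Msr1 on chromosome 8, so they are not separate checks. Such genes could also follow batch or strain, so their values cannot decide whether single labels, or all of them, are wrong. An exchange of all labels would give the same 15 of 15 mutant-labelled arrays above every wild-type-labelled one as a targeted allele that still makes a detected transcript, so the 2 cannot be told apart. More macrophages, the biological explanation, were not borne out, with a macrophage list median of 0.026 over all times.

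Redrawing which arrays belong to which group gave as many calls as the real grouping in 1 of 10 splits for each of the 13 comparisons of 3 against 3 arrays, the real split being that 1, and 10 splits are too few to exclude chance. The highest count of any other split was 0 for the wild-type-labelled arrays at 2, 8 and 16 h, the mutant-labelled arrays at 16 h and the genotypes at 0 and 8 h. It was 1 for wild type at 48 h, mutant at 8 h and the genotypes at 16 h, 4 for mutant at 48 h and 20 for the genotypes at 48 h. For the comparisons with the mutant-labelled 2 h arrays it was 104 against 0 h and 65 between genotypes. With genotype labels redrawn within each time, 1 of 100 draws, the real one, reached 2485 probe sets over all times and 1026 for the interaction, and the highest others were 150 and 258. Such draws remove every genotype difference, so they cannot test the interaction apart from the average difference. The odds ratio near Msr1 was reached by 2 of 100 draws, the real one among them, with a highest other value of 4.69. A redraw without any call was scored as 0, and no redraw called more than 150 probe sets, against 2485 in the real grouping. The 2 of 100 may thus reflect how few calls the redraws made, and cannot decide whether the clustering near Msr1 is chance. The 72 list calls were reached by 26 of 100 draws, the real one among them and the highest at 116, so the number of list calls as a whole may be chance.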

How the results depend on the processing

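Of values for named genes, 6618 were unchanged under the alternatives other than leaving out single arrays, 18 were stronger, 584 weaker and 4 reversed. Unchanged means the same side of the threshold, and the same direction where past it. The direction of values past the threshold in neither fit was not compared. With single arrays left out 7687 were unchanged in this sense, 14 were stronger, 1275 weaker and 0 reversed. Over all times Obp1a, Mt1 and Mt2 reversed under quantile normalization, to -0.08, -0.03 and -0.03, and Omp reversed to 0.36 without the mutant-labelled 2 h arrays, whose low Omp signal is no longer in the mean. Below, wild type and mutant stand for arrays so labelled, and the cause of each change was not tested.

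Quantile normalization gave 104 calls for wild type 2 h and 22 for wild type 8 h, against 40 and 14. A variance trend with robust moderation gave 71 for wild type 2 h. With only the groups compared in the fit, fewer arrays estimate the spread: counts were 0 for wild type 8 h (531 at an unadjusted limma p under 0.05), 738 for wild type 16 h, 31, 145 and 204 for mutant 2, 16 and 48 h, and 23, 14, 373 and 339 between genotypes at 2, 8, 16 and 48 h. Without the mutant 2 h arrays they were 132 for wild type 2 h, 477 between genotypes at 8 h and 415 for the interaction. With only replicate 2 of them, counts were 320 for mutant 2 h and 203 between genotypes at 2 h. List calls went from 72 to 10 with an estimated correlation. The odds ratio near Msr1 was 1.40 within 40 Mb.

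The replicate number as a block gave 15 calls for wild type 2 h in place of 40 and moved no other count by over 1.5 times. Deviations from group means correlated between arrays of the same number with a median of -0.01 (-0.35 to 0.35), and 6 of 30 arrays were closest to their own number, so the data give no hint of pairing.

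With 1 array left out in turn, wild type at 2, 8, 16 and 48 h had 0 to 32, 0 to 93, 164 to 269 and 572 to 919 calls, and mutant 510 to 1573, 52 to 92, 102 to 192 and 344 to 839. Genotypes at 0, 2, 8, 16 and 48 h had 648 to 1033, 277 to 981, 47 to 290, 223 to 491 and 631 to 1189, over all times 2283 to 2686, and the interaction 676 to 1336.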

Other observations

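Families outside the fixed lists were tested too, chosen after the values were seen, in the fit without the mutant-labelled 2 h arrays. Their camera p-values were adjusted over these families alone, so they overstate the support. Over all times stands here for the average of 0, 8, 16 and 48 h of both labels. Genes of oxidative phosphorylation, the mitochondrial machinery of energy production, were higher in the mutant-labelled arrays over all times in 43 of 65 cases and lower in 5, with a median of 0.22, or 0.18 after quantile normalization (camera adjusted p = 3.20e-14, adjusted p = 0.0629 with an estimated correlation). At 0 h 34 were higher and 3 lower (median 0.31, camera adjusted p = 5.62e-14, estimated-correlation adjusted p = 0.0478). In the wild-type-labelled arrays 14 of them rose at 2 h (median 0.26, camera adjusted p = 1.18e-17, estimated-correlation adjusted p = 0.0394). That rise and the difference at 0 h use the same wild-type-labelled 0 h arrays, so they are not independent. The rise did not last: none passed at 8 h, 1 rose and 2 fell at 16 h, and 7 fell with none up at 48 h (median -0.07). Immunoglobulin genes were higher over all times in 8 of 10 cases and lower in 1, with a median of 1.19 (camera adjusted p = 5.01e-06, adjusted p = 0.0643 with an estimated correlation). At 8 h 1 of the 10 was higher, and at 16 h none differed (median 0.24, camera adjusted p = 0.283).

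Proteasome genes, which degrade tagged proteins, had a median change of 0.19 at 8 h in the wild-type-labelled arrays, with 31 of 34 positive and none past the threshold (camera adjusted p = 4.40e-11, estimated-correlation adjusted p = 0.0301). At 8 h in the mutant-labelled arrays the median was 0.09, with 28 positive (camera adjusted p = 0.00269, adjusted p = 0.338 with an estimated correlation). At 16 h 6 rose in the mutant-labelled arrays (median 0.21, camera adjusted p = 9.95e-08, adjusted p = 0.099 with an estimated correlation). In the wild-type-labelled arrays 4 rose at 16 h (median 0.17, camera adjusted p = 1.47e-05, adjusted p = 0.146 with an estimated correlation). The median difference of changes was -0.06 at 8 h and 0.06 at 16 h (camera adjusted p = 0.0499 and 0.532). Of 7 olfactory receptor genes measured, 3 fell at 48 h in the wild-type-labelled arrays (median -0.40, camera adjusted p = 0.0144, adjusted p = 0.103 with an estimated correlation).

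Ighm, of antibody-secreting cells, varied between groups without a steady course. The wild-type-labelled means at 0, 2, 8, 16 and 48 h were 74.8, 851.5, 680.5, 1883 and 62.4, and the mutant-labelled means 3296, 1076, 2020, 1895 and 2572 (n = 3 arrays each). Of the 1277 probe sets that differed between genotypes at 0 h, 39 were called in the same direction at 0, 8, 16 and 48 h, 18 higher and 21 lower, and 830 had the same sign at 8, 16 and 48 h.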
